A study of Mus musculus with 6 samples.

How the data were processed

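RNA of mouse splenic B cells was measured on 6 single-colour Illumina bead arrays, 3 in the control group (normal B cells) and 3 in the TRAF3KO group (premalignant B cells lacking TRAF3), as grouped by the labels. Per the labels' protocols, RNA was extracted with Trizol, cleaned on columns with DNase treatment and checked on a Bioanalyser, and biotin-labelled cRNA was made with an Ambion kit. BeadStudio 3.2.3 is named in the submitters' processing notes, without its role. How the control mice were related to the TRAF3KO mice, whether each array held a separate mouse, and which part of Traf3 was deleted are not given in the sources used here. The p-values therefore measure the spread between these samples, which may be in part technical.

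The table the authors deposited holds log2 intensities of 25697 probes on each array. Medians of the arrays differed by at most 0.00705, and all intensities under 1000 were multiples of 0.1 within 0.001. The lowest value is 0, an intensity of 1, and the next intensity is 1.1. Between 8049 and 8065 probes of each array lay at this floor (31.3% to 31.4%), 3999 probes on all arrays and 7648 on some. Which background correction, normalisation and floor were applied is not given in the sources used here, and no detection p was used. No sequencing depth applies to arrays, and their number limits the precision.

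Probes were named through the platform annotation of the array. It gave 1 gene symbol for 23141 probes and several for 0 probes, and the other 2556 probes are unnamed here. The order of neighbouring genes was taken from RefSeq on GRCm38.p6, in which 10302 of the tested genes were placed and 2 were not. Because no genome build is named for the arrays, no coordinates are given. No probe carried the symbol Traf3, Mcc or Etnk1, and those genes were not analysed here.

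The design, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Probes were kept when they lay above the 40th percentile of their array on at least 3 of the 6 arrays, which left 15657 probes. The values were used as deposited, since the array medians were within the 0.1 allowed for that. Each probe was fitted with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with group as the only term. The p-values were adjusted by the Benjamini-Hochberg method over all kept probes, or over genes where the mean of a gene's probes was fitted. A gene with several kept probes was represented by the brightest, and took the adjusted p of that probe. A gene was called at an adjusted p under 0.05. Where every array of a group lay under the 40th percentile (on average log2 3.96, an intensity of 15.6), the difference is given as a lower bound against that level.

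The named genes were the 12 largest differences in each direction among called genes whose groups did not overlap, up to 4 called members of each list (or 2 members where none was called), and 22 genes fixed by name. No predicted or clone-named gene had to be skipped. The 34 gene lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the 33 lists with at least 5 tested members. Counts of called members are given with p adjusted over all kept probes and with p adjusted over the list alone. An estimated correlation and the rotation test fry were alternatives. Other alternatives were other normalisations, filters, variance models and array weights, the replicate number as a block, the mean of a gene's probes, a linear model per probe without variance moderation, and leaving out each array. Offsets of 16, 50 and 150, raising low values to the 40th percentile, and inferred sex as a block were added after the values were seen. Sex was inferred from Xist and Eif2s3y, because the labels do not give it.

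The procedure was tested on simulated data of the 15657 kept probes, with a change planted in 1 probe of each of 200 genes among 10304. It recovered 26%, 58%, 58% and 76% of the genes changed by log2 0.5, 1, 2 and 4, and 54.2%, 93.3%, 96% and 96.7% of those with a mean of log2 8 or more. Of its 114 called probes, 5 were false calls (4.39%). A list with a planted change was recovered, and 0 of the 19 lists sharing no gene with it passed. The simulated probes were drawn independently of each other, so lists whose genes vary together were not tested.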

Results

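The data were log2 intensities from 6 arrays of mouse splenic B cells, 3 of control cells and 3 of TRAF3KO cells. TRAF3 is an adaptor protein that restrains non-canonical NF-kB signalling and B cell survival, and mice whose B cells lack it can develop B cell lymphoma. The design asks which genes differ between premalignant cells without TRAF3 and normal B cells. Traf3 itself was not analysed here, as no probe carried its symbol, so the arrays give no check of the knockout.

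In the TRAF3KO cells 9 of 22 NF-kB pathway genes and 4 of 11 anti-apoptotic genes were higher and 0 of either list lower. Birc3 was counted in both. Both lists passed camera and fry (fry adjusted p = 0.0027 and 0.040), but not camera with an estimated correlation (adjusted p = 0.19 and 0.35). Nfkb2, which encodes the NF-kB subunit precursor p100, rose from 7.90 ± 0.37 to 9.64 ± 0.11 (log2 intensity, mean and SD, n = 3), and Il9r, the interleukin 9 receptor, rose from 8.16 ± 0.53 to 12.79 ± 0.28. Cxcr4, a chemokine receptor, fell from 13.05 ± 0.09 to 11.95 ± 0.06, and Sdc1, the plasma cell marker CD138, fell from 8.47 ± 0.08 to 6.26 ± 0.21. Of 10304 genes tested, 457 were called, 237 higher and 220 lower in TRAF3KO, and 102 of them differed at least 2-fold (63 higher, 39 lower). All 457 had groups that did not overlap, which a call with 3 arrays per group nearly requires, so this adds no support to the calls. Of all tested genes 22.4% had groups that did not overlap, against 10% by chance. Leaving out any 1 array left fewer samples and fewer calls. The count was 227, 382 and 287 genes without control replicates 1, 2 and 3. It was 282, 278 and 342 without TRAF3KO replicates 1, 2 and 3. A loss of power and a dependence on single arrays are not told apart by these counts. With no trend in the variance model 65 genes were called, with no filter on dim probes 114, and by a linear model per probe without variance moderation 37.

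**Figure D1:**
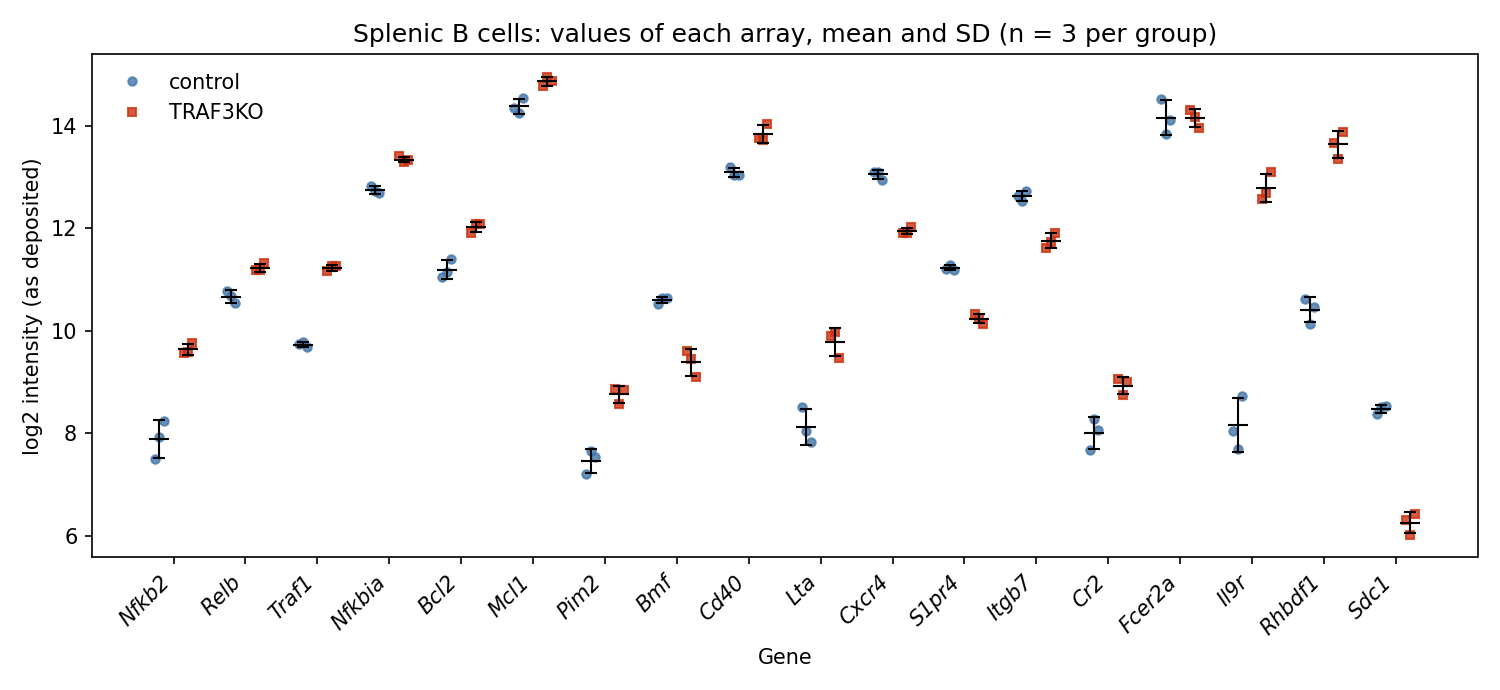
Log2 intensity (vertical axis) of 18 named genes on each of the 6 arrays, with circles for control, squares for TRAF3KO, and bars for the mean and SD of 3 arrays. Nfkb2, Traf1, Bcl2 and Il9r lie higher and Cxcr4, S1pr4 and Sdc1 lower on every TRAF3KO array, while Fcer2a overlaps (14.16 against 14.15).

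Arrays of a group were more alike than arrays of different groups: Pearson's r across probes was 0.920 to 0.925 within control, 0.922 to 0.930 within TRAF3KO and 0.910 to 0.918 between groups (probes are not independent replicates). The first principal component, with 25.6% of the variance, separated the groups, and the second, with 20.6%, set control replicate 2 apart (-90.7) and also parted the arrays by inferred sex (30.9 to 43.3 in males, -7.44 and -17.8 in the other females). By Xist and Eif2s3y, control replicates 1 and 3 and TRAF3KO replicate 1 were male and the other 3 arrays female. With inferred sex as a block 319 genes were called, 304 of them among the 457.

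The NF-kB list of pathway components had 9 of 22 tested members higher and 0 lower (10 and 0 adjusted over the list alone). Its adjusted p was 1.2e-07 by camera, 0.19 with an estimated correlation and 0.0027 by fry. Traf1, a TNF receptor adaptor, rose from 9.73 ± 0.05 to 11.23 ± 0.06 (SD; adjusted p = 9.4e-06). Nfkb2 rose by 1.74 ± 0.18 (log2 difference and SE, the form used for all differences; adjusted p = 4.9e-04), and Nfkbia, an inhibitor of NF-kB that is itself induced by it, rose by 0.59 ± 0.07 (adjusted p = 7.9e-04). Relb, the partner of the p100 product p52, rose by 0.57 ± 0.09 (adjusted p = 0.0070). Map3k14, which encodes the kinase NIK, differed by 0.17 ± 0.10 (adjusted p = 0.45) and Traf2 by 0.82 ± 0.22 (adjusted p = 0.067, under 0.05 only with an offset of 150), neither called. Of the NF-kB target genes, 15 of 29 were higher and 0 lower (22 and 1 adjusted over the list alone). Their adjusted p was 3.7e-17 by camera, 0.16 with an estimated correlation and 0.0027 by fry. They included Lta, a lymphotoxin, at 1.65 ± 0.20, Ebi3, a cytokine subunit, at 1.01 ± 0.11, and Cd40, the costimulatory receptor, at 0.75 ± 0.09. Both NF-kB lists share 7 called genes.

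Of 11 tested anti-apoptotic genes 4 rose and 0 fell (5 and 0 adjusted over the list alone). Of the 4, Birc3 and Pim2 are also in the list of NF-kB target genes, and Birc3 is also a pathway component, so the lists are not independent. The list had an adjusted p of 1.9e-04 by camera, 0.35 with an estimated correlation and 0.040 by fry. Bcl2 rose by 0.83 ± 0.10, Mcl1 by 0.48 ± 0.08 and the kinase Pim2 by 1.29 ± 0.18. Birc3 rose by 0.83 ± 0.18 (adjusted p = 0.026), a call lost in 5 of the 6 fits that left out 1 array and with inferred sex as a block. Bcl2l1 differed by -0.26 ± 0.18 (adjusted p = 0.55). Among 8 pro-apoptotic genes, Bmf fell by 1.22 ± 0.13 while Bbc3 rose by 1.11 ± 0.23 and Bid by 0.70 ± 0.15, and the list did not pass (adjusted p = 0.62; 3 higher and 1 lower adjusted over the list alone). Bbc3 and Bid lost their calls in 4 and 5 of the 6 fits that left out 1 array, and Bid also with inferred sex as a block.

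Marginal zone markers had 5 of 13 members higher and 0 lower (7 and 0 adjusted over the list alone). Their adjusted p was 8.0e-05 by camera, 0.23 with an estimated correlation and 0.033 by fry. Asb2 rose by 1.95 ± 0.20, Marcks by 0.61 ± 0.08 and Cr2, the complement receptor CD21, by 0.92 ± 0.18 (adjusted p = 0.019, lost in 4 of the 6 fits that left out 1 array and with inferred sex as a block). Cd1d1, Dtx1 and Notch2 were not called, at 0.07 ± 0.07, 0.25 ± 0.15 and -0.41 ± 0.38. Follicular markers had 4 of 10 members lower and 2 higher (5 and 2 adjusted over the list alone). Their adjusted p was 0.018 by camera, 0.35 with an estimated correlation and 0.040 by fry. S1pr4, a sphingosine phosphate receptor, fell by 0.99 ± 0.09, the integrin Itgb7 by 0.88 ± 0.09 and the transcription factor Klf2 by 0.42 ± 0.08, while Cxcr5 rose by 0.35 ± 0.07. The calls of Klf2 and Cxcr5 were each lost in 4 of the 6 fits that left out 1 array. Fcer2a (CD23) differed by -0.01 ± 0.15 (adjusted p = 0.99). The follicular list was no longer called with inferred sex as a block (adjusted p = 0.060), without control replicate 3 (0.061), without a trend (0.066) and with the mean of probes (0.055), over a range of 0.0053 to 0.35.

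B-1 cell markers had 3 of 15 members higher and 0 lower (5 and 0 adjusted over the list alone; camera adjusted p = 0.0038, adjusted p = 0.35 with an estimated correlation and 0.16 by fry). These were Cd80 at 1.55 ± 0.29, Pdcd1lg2 (PD-L2) at 0.99 ± 0.23 and Tbc1d9 at 0.96 ± 0.21. Cd80 is also in the list of NF-kB target genes. Pdcd1lg2 and Tbc1d9 each lost the call in 5 of the 6 fits that left out 1 array and with inferred sex as a block, and Cd80 in 2 of the 6. Ptpn22 differed by 0.28 ± 0.09 (adjusted p = 0.13, called only without TRAF3KO replicate 3). The plasma cell and secretory list had 3 members of 17 higher and 1 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.35 with an estimated correlation and 0.12 by fry). Xbp1, Herpud1 and Pdia4, which serve protein folding and secretion, rose by 0.48 ± 0.08, 0.43 ± 0.06 and 0.65 ± 0.12, while Sdc1 fell by 2.22 ± 0.21. Sdc1 was called in each alternative, with differences from -3.49 to -1.16. Pdia4 lost its call in 1 of the 6 fits that left out 1 array, without TRAF3KO replicate 2 (adjusted p = 0.051). Pan-B markers did not pass (adjusted p = 0.50, median -0.01), with Pou2af1 higher by 0.75 ± 0.08 and Fcrla lower by 0.32 ± 0.06, lost in 3 of the 6 such fits (2 higher and 3 lower adjusted over the list alone). Germinal centre markers had 0 of 9 called (1 adjusted over the list alone; adjusted p = 0.99; camera direction up, median -0.11), with Gcsam at -1.70 ± 1.42. The immunoglobulin list had 2 tested members, Vpreb1 at 1.86 ± 2.43 and Jchain at -0.03 ± 0.59, and was not tested.

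**Figure D2:**
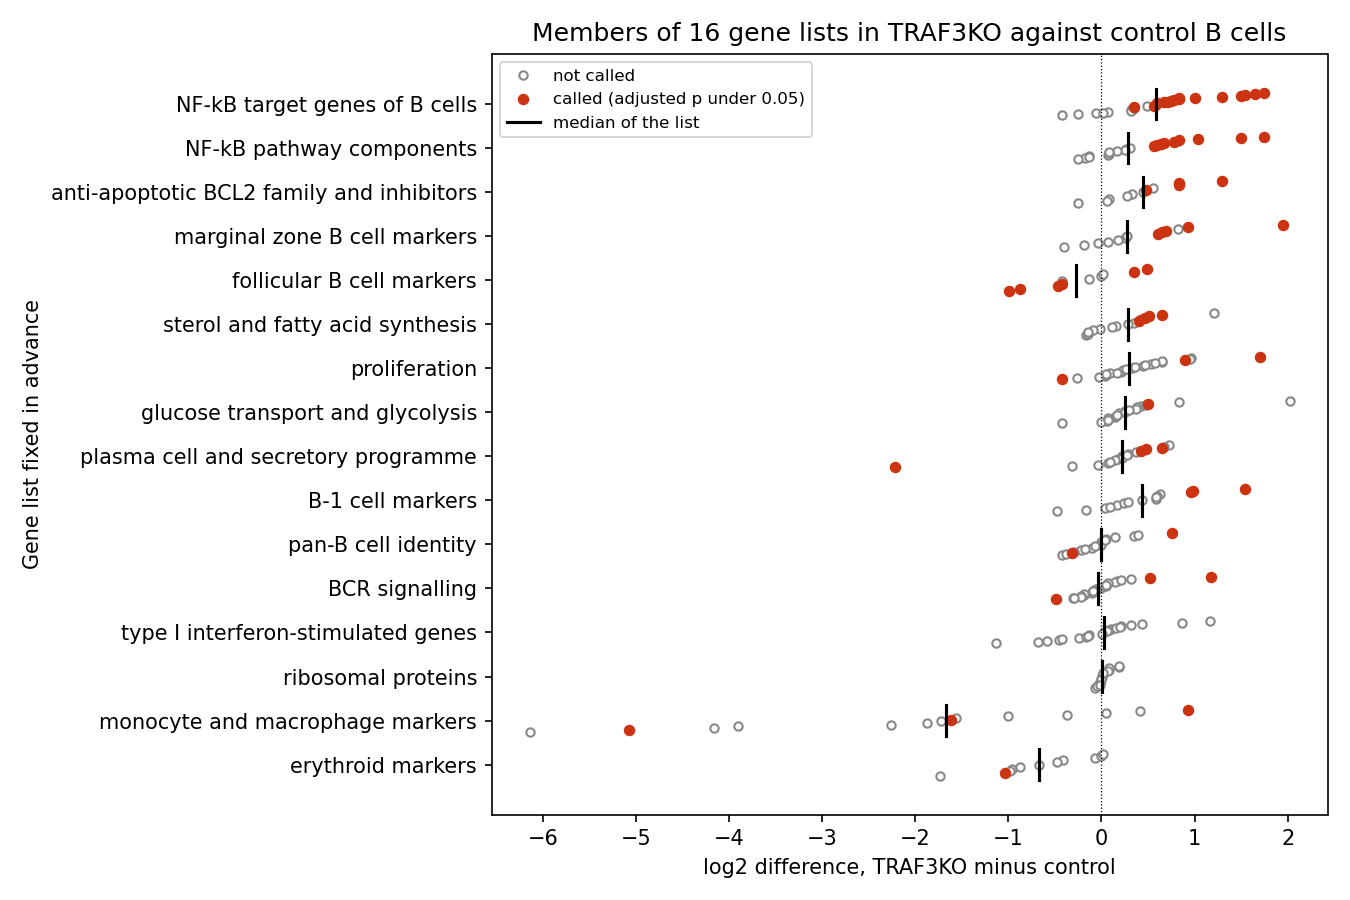
Log2 difference, TRAF3KO minus control (horizontal axis), of each tested member of 16 gene lists (rows); filled points were called, open points were not, and the bar is the median. NF-kB targets have a median of 0.58 with 15 of 29 members called, and the pan-B list has a median of -0.01.

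Of 24 proliferation genes 2 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 6.6e-04, adjusted p = 0.58 with an estimated correlation and 0.22 by fry). Tk1, a thymidine kinase, rose by 1.70 ± 0.12 and Tyms by 0.90 ± 0.21, while Cenpa, a centromere histone, fell by 0.42 ± 0.09. Tyms and Cenpa lost their calls in 5 and 4 of the 6 fits that left out 1 array, and both with inferred sex as a block. Of 15 sterol and fatty acid synthesis genes 4 rose and 0 fell (6 and 0 adjusted over the list alone). The sterol list had an adjusted p of 0.0024 by camera, 0.22 with an estimated correlation and 0.0020 by fry. Its members included Hmgcs1 at 0.51 ± 0.06, Fdps at 0.47 ± 0.07 and Sqle at 0.40 ± 0.08, the last not called without control replicate 3 (adjusted p = 0.057). Of 19 glycolysis genes, Slc2a3, a glucose transporter, alone rose, by 0.50 ± 0.11 (2 adjusted over the list alone; camera adjusted p = 0.0063, adjusted p = 0.62 with an estimated correlation and 0.47 by fry). Slc2a3 lost its call in 4 of the 6 fits that left out 1 array. That list was no longer called without control replicate 1 (adjusted p = 0.057), control replicate 2 (0.089) or TRAF3KO replicate 1 (0.35). Slc2a1 differed by 0.05 ± 0.19 (adjusted p = 0.92) and Hk2 by 0.83 ± 0.24 (adjusted p = 0.088, called with inferred sex as a block and without control replicate 3, lowest 0.025). In the choline and phospholipid list, which did not pass (adjusted p = 0.62), Lpcat1 rose by 1.00 ± 0.20 and Sgms1 and Chkb fell by 0.75 ± 0.09 and 0.43 ± 0.10 (2 higher and 3 lower adjusted over the list alone). Lpcat1 and Chkb lost their calls in 3 and 4 of the 6 fits that left out 1 array. Chkb also lost its call with inferred sex or the replicate number as a block. Chka differed by 1.66 ± 0.71 (adjusted p = 0.28). Cell cycle control genes did not pass (adjusted p = 0.056), with Gadd45a and Cdkn2d lower by 0.45 ± 0.08 and 0.61 ± 0.13 and 3 lower adjusted over the list alone. That list passed without control replicate 1, control replicate 2 or TRAF3KO replicate 1 (lowest adjusted p = 0.028). Gadd45a was not called without control replicate 3 (adjusted p = 0.0501), and Cdkn2d in 4 of the 6 fits that left out 1 array or with inferred sex as a block. The mitochondrial list had 0 of 24 called and the ribosomal list 0 of 16 by limma (adjusted p = 0.26 and 0.62).

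Unlike the NF-kB pathway list, the other signalling lists did not pass as groups in the planned fit, though single members of most of them changed. The TNF family list passed in 7 of 22 alternatives, among them the 3 offsets and inferred sex as a block (lowest adjusted p = 0.020). The immediate early list passed with inferred sex as a block and without TRAF3KO replicate 2 (lowest adjusted p = 0.0032), and the chemokine list without control replicate 1 (0.029). In B cell receptor signalling (adjusted p = 0.62), Rasgrp3, a Ras activator, rose by 1.17 ± 0.08 and Bcl10 by 0.52 ± 0.07, while the inhibitory receptor Fcgr2b fell by 0.49 ± 0.07 (2 higher and 3 lower adjusted over the list alone; median -0.03, mean 0.02). Dgkz differed by -0.30 ± 0.08 (adjusted p = 0.087). In the JAK-STAT list (adjusted p = 0.13), Jak3 rose by 1.04 ± 0.07 and Il10 by 2.99 ± 0.63 (1.57 with an offset of 50), and Il10ra fell by 0.42 ± 0.10 (5 higher and 1 lower adjusted over the list alone). Il10 and Il10ra lost their calls in 4 and 5 of the 6 fits that left out 1 array, and both with inferred sex as a block. TNF family genes (adjusted p = 0.056) had 4 members higher, with Ltb at 0.71 ± 0.11, and Tnfrsf13b lower by 0.46 ± 0.10, lost in 5 of the 6 such fits (4 and 2 adjusted over the list alone). Tnfrsf13c, the BAFF receptor, differed by -0.32 ± 0.11 (adjusted p = 0.16, called only without TRAF3KO replicate 3). Among chemokine and adhesion genes (adjusted p = 0.19), Cxcr4 fell by 1.10 ± 0.07 and Ccr6 rose by 0.66 ± 0.09 (3 higher and 5 lower adjusted over the list alone). Antigen presentation genes (adjusted p = 0.14) included Ctss, higher by 0.66 ± 0.11 (3 adjusted over the list alone). Ly96 of the toll-like receptor list (adjusted p = 0.21; median 0.08, mean -0.06) rose by 0.89 ± 0.21, lost in 5 of the 6 such fits and with inferred sex as a block (2 adjusted over the list alone), and Dusp6 of the immediate early list (adjusted p = 0.19) by 0.60 ± 0.09 (1 adjusted over the list alone; not called with the mean of probes, adjusted p = 0.061). Interferon-stimulated genes had 0 of 21 called by limma (adjusted p = 0.94; median 0.03, mean -0.01), with Rsad2 at -1.13 ± 0.57.

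The largest differences included genes near the floor of the arrays. Il9r rose by 4.63 ± 0.23 (adjusted p = 2.4e-06), Rhbdf1, an inactive rhomboid protease, by 3.23 ± 0.14 (adjusted p = 1.6e-06), Klk4 by 3.09 ± 0.24, Chst10 by 2.66 ± 0.22, Plcd3 by 2.64 ± 0.32 and Cd59a by 2.62 ± 0.19. Zbtb46, a transcription factor, lay at the floor on all 3 control arrays and was at least 6.35-fold higher in TRAF3KO (adjusted p = 0.024). Its call was lost with inferred sex as a block and without any 1 of the 3 TRAF3KO arrays (adjusted p up to 0.23). Nrep (6.13 ± 1.17), Hspg2 (from 2.89 to 8.90), Gpr34 (5.51 ± 0.86) and Ffar2 (3.37 ± 0.82) had dim control arrays, and their log2 differences shrank to 2.14, 3.06, 3.10 and 1.81 with an offset of 50. Lower genes were C1qc (-5.08 ± 1.24), Tsc22d1 (-3.58 ± 0.60), Wfdc17 (-3.46 ± 0.70), Eya1 (-2.83 ± 0.69) and Pltp (-2.25 ± 0.24). Nxnl2, Ngfr, Anxa3, Col27a1, Tmem51 and Lyz2 fell, with differences of -2.03, -1.89, -1.77, -1.72, -1.65 and -1.61. With an offset of 50 the differences of C1qc, Tsc22d1, Eya1, Nxnl2 and Anxa3 were -2.05, -1.66, -1.32, -1.20 and -1.17. Calls were lost in 5 of the 6 fits that left out 1 array for Eya1 and Lyz2, in 4 for C1qc, Ffar2 and Anxa3, in 3 for Nrep, Wfdc17 and Nxnl2, in 2 for Tsc22d1 and in 1 for Ngfr. Eya1, Anxa3, Wfdc17 and Nxnl2 were also lost with inferred sex as a block, and Eya1 with the replicate number as a block. With robust eBayes the calls of Hspg2, Gpr34, Ffar2, C1qc, Lyz2 and Wfdc17 were lost. With the mean of probes the calls of Bbc3, Bid, Tbc1d9, Tyms, Chkb, Il10ra, Ly96, C1qc, Lyz2, Eya1, Ffar2 and Nxnl2 were lost.

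Markers of other cell types were measured in the same samples. Monocyte and macrophage markers were lower as a group (median -1.67; camera adjusted p = 0.0038, adjusted p = 0.53 with an estimated correlation and 0.32 by fry), with C1qc and Lyz2 lower and Spic, a macrophage and B cell transcription factor, higher by 0.93 ± 0.18 among 14 tested (5 lower and 1 higher adjusted over the list alone). The list was not called with no filter on dim probes (adjusted p = 0.058) or a filter at the 60th percentile (0.28), C1qc and Lyz2 lost their calls in 4 and 5 of the 6 fits that left out 1 array, and Spic was not called without TRAF3KO replicate 1 (0.077). Erythroid markers were lower (median -0.67; camera adjusted p = 0.034, adjusted p = 0.37 with an estimated correlation and 0.15 by fry), with Car2 alone called of 11, lower by 1.03 ± 0.23 (1 adjusted over the list alone) and lost in 5 of the 6 fits that left out 1 array. The erythroid list was not called without control replicate 3 (0.14) or TRAF3KO replicate 1 (0.33), with no filter (0.10), a filter at the 60th percentile (0.066), the mean of probes (0.052) or low values raised to the 40th percentile (0.054). Hba-a1, a haemoglobin chain, lay at 16.12 and 16.05 in the groups, near the top of the scale (16.15). Dendritic cell markers did not pass camera (adjusted p = 0.50) but passed by fry (adjusted p = 0.0098). Tcf4, higher by 0.43 ± 0.07, and Zbtb46 were called higher and Cst3 fell by 0.62 ± 0.08 (2 higher and 1 lower adjusted over the list alone). By limma, 0 genes were called, also adjusted over the list alone, among 12 T cell (adjusted p = 0.81; median 0.04, mean -0.55), 8 NK cell (0.85), 9 granulocyte (0.94), 5 platelet (0.50) and 5 stromal markers (0.55).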

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

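The tests on chromosome neighbourhood, the Traf3 locus, second probes, sex, macrophage markers and B cell subsets were chosen after the values were seen. For splits of the arrays, and for second probes and sex at Il9r and its neighbours, the expected outcomes were written down before those tests were run.

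Among 1446 kept probes without a listed gene, 60 changed, 37 higher and 23 lower in TRAF3KO, a rate about that of all kept probes (638 of 15657). The probe with the smallest adjusted p rose by 2.42 (from 12.04 ± 0.31 to 14.46 ± 0.14, n = 3, limma).

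The 457 called genes were set against other splits of the 6 arrays. Of the 10 splits into 3 and 3, 1 gave as many, the real one, and the highest of the others gave 2; with 10 splits the share cannot fall under 0.1.

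Il9r, Snrnp25 and Rhbdf1, neighbours in the gene order, rose by 4.63, 2.21 and 3.23, and the next gene, Mpg, by 0.93. Nprl3, the gene after Mpg, differed by 0.53 ± 0.13 and was just short of a call (limma adjusted p = 0.0506). Against a strain difference around Traf3, 0 of the 3 genes lie on its chromosome. That does not address a strain difference at other places, as the relation of the mice is not given. Against sex, the differences kept at least 0.971 of their size with inferred sex as a block. A regional change may be involved but cannot be told apart from changes of single genes. To test a variant under a probe, 0 second probes were measured. Of the 20 genes around the 3, only Mpg was called (permutation p = 0.571), a count that a short block of genes would hardly raise. A further test was added after that one had left the question open and the run of neighbours had been seen: a run of 4 called neighbours arose in 62 of 10000 brightness-matched permutations (p = 0.0063), which does not count as independent evidence. A biological effect of losing TRAF3 stays open.

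Macrophage markers were lower in TRAF3KO, with a median of -1.59 over the 12 above the dim bound on all control arrays. Fewer macrophages in the TRAF3KO samples could account for this. Of these markers 75% were lower, with Spic, Adgre1 and Ms4a7 not lower, under the 80% set after the values were seen. Spic is also a B cell gene, so its rise does not count against fewer macrophages, and the share cannot decide. Sex could account for part: the median kept 0.693 of its size with inferred sex as a block, between the bounds set for and against it, so these explanations cannot be told apart here. Within males the mean of the markers was 8.40 and 8.78 in control and 7.42 in TRAF3KO, and within females 7.16 against 5.97 and 5.48. Much of the fall in females lay in markers at or near the floor in TRAF3KO. Slc40a1 went from 6.09 to 0 and 0, Cd14 from 4.31 to 0 and 0, and C1qc from 5.40 to 2.17 and 0. Among brighter markers in females, Lyz1 fell from 10.91 to 10.40 and 9.82, while Adgre1 went from 9.96 to 10.33 and 9.59. With sex as a block 4 markers were called lower against 2 without, a count looked at after the ratio was known.

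Of the marginal zone markers 5 of 13 were called higher, and of the follicular markers 4 of 10 lower and 2 higher. The adjusted p was 0.23 and 0.35 with an estimated correlation, and 0.033 and 0.040 by fry. A larger share of marginal zone cells could account for this and stays open. The 95% interval of Fcer2a reaches down to -0.331, past the median of all tested follicular markers (-0.28), which includes Fcer2a itself. The interval does not reach the median of the 4 called lower (-0.67), which were picked by their change. Cd1d1 of the marginal zone list did not rise (0.07 ± 0.07), and Cxcr5 and Fchsd2 of the follicular list rose. Non-B cells would lower the pan-B markers together. Their median was -0.00817, with Cd79a at -0.007 ± 0.060, Cd79b at -0.002 ± 0.056 and Ms4a1 at 0.020 ± 0.091. By the rule set for it this test cannot decide, because pan-B members were called in both directions. The values argue only against a dilution as large as the called follicular falls (-0.67), a size picked by those falls. A smaller dilution stays open, since Fcrla was called lower (-0.32 ± 0.06) and Vpreb3 lay at -0.43 ± 0.12, while Pou2af1 was called higher. A change of expression within B cells is not told apart from these.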

How the results depend on the processing

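The offsets, raising low values to the 40th percentile and sex as a block were chosen after the values were seen; the other alternatives were planned. Of the 457 called genes 453 kept their sign with the mean of probes; groups that do not overlap leave little room for a turned sign in the other fits. The count was 456 with cyclic loess, 526 with a filter at the 60th percentile, 562 with robust eBayes, 472 with array weights, 386 with the mean of probes, 513, 527 and 529 with offsets of 16, 50 and 150, 493 with low values raised and 319 with sex as a block. It moved to 114 with no filter on dim probes (62 higher, 52 lower; 82 shared), 65 without a trend (39, 26; 47 shared), 37 without variance moderation (25, 12; 24 shared; 67.6% higher against 51.9%) and 102 at a log2 difference of at least 1 (63, 39). With no filter the prior degrees of freedom fell from 6.72 to 0.676 and without a trend to 1.09, so that the variances were moderated less. Leaving out 1 array gave 227 to 382 genes (131 to 211 higher, 96 to 171 lower) with fewer samples, and 46 of the 83 called named genes kept the call in all 6 fits. Of these 83, 59 lost the call with no filter, 66 without a trend and 72 without variance moderation. Nfkb2, Relb, Bcl2, Mcl1, Pim2 and Cd40 were among them each time. Of the 12 lists, 0 passed with an estimated correlation and 7 lists passed by fry, 6 of them among the 12. The cause was not tested. A higher correlation between genes cannot account for the loss of the sterol list. Its correlation was estimated at -0.061, under the preset 0.01, yet its adjusted p by camera went from 0.0024 to 0.22. The other passing lists had estimates over 0.01. Whether the replicate numbers pair arrays is not given in the sources used here. In deviations from the group means, same-numbered arrays correlated at r = 0.044, 0.043 and 0.030. Each array correlated best with its own number, a hint from the data. With the replicate block 468 genes were called, 410 shared. The planned offsets and floor applied to linear values only and were not run as written. Signal over background limits dim genes: the median SD was 1.15 under log2 6 and 0.0976 over 12.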

Other observations

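The genes and groups here, and their tests, were chosen after the values were seen. Single genes outside the lists also changed. Il12a, an interleukin 12 subunit, rose by 1.73 ± 0.11 (SE, n = 3, limma adjusted p = 2.1e-05), Kynu, an enzyme of tryptophan breakdown, by 1.56 ± 0.09, Pglyrp1 by 1.31 ± 0.09, the nuclease Dnase1l3 by 1.36 ± 0.11 and Cd274 (PD-L1) by 0.69 ± 0.17 (adjusted p = 0.044). Csrp2 fell by 1.48 ± 0.10, Sgk1, a kinase, by 1.30 ± 0.13, Cd93 by 1.20 ± 0.15 and Il18 by 1.07 ± 0.14.

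Histone genes were lower: 10 of 57 fell and 0 rose (median -0.39; camera p = 5.7e-11, p = 0.021 with an estimated correlation, unadjusted and on a group picked from these data). H3c7 fell by 1.43 ± 0.28, H2bc9 by 0.82 ± 0.14 and H2bc12 by 0.77 ± 0.13. Of 61 genes for carbohydrate and sulphate transferases, 2 rose and 7 fell by limma, and the group did not pass camera. Called genes lay next to each other in 34 pairs of the same direction, against a median of 10 in brightness-matched permutations (p = 0.0001, the smallest they can give), among them Ltb, Tnf and Lta.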
